A study of Mus musculus with 14 samples.

How the data were processed

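Polyadenylated RNA of FoxP3-YFP-positive Tregs, sorted directly from spleen and from MC38 flank tumors of mice, was measured in 14 libraries: 4 WT and 3 Il23r Flox libraries per tissue, as the labels group them. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy Plus micro kit and libraries were made by GeneWiz for ultra-low input. The authors deposited 1 table of raw read counts per gene, not normalized, with 27179 genes and 14 columns, each matched to a sample by its name. The submitters' processing notes name the genome build mm10. The aligner, the counting tool, the annotation, the strand setting and the exons deleted in the Flox allele are not given in the sources used here. Reads shared between overlapping or antisense genes or near-identical copies could therefore not be separated. Gene IDs were matched to symbols and to GRCm38.p6 coordinates in the NCBI RefSeq annotation (25275 IDs), and 18 further IDs through GENCODE M21. The 1886 unmatched IDs, with 1.25 to 1.94% of a library's counts, stayed in the tests and were not named.

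Counts as deposited were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM normalization, filterByExpr by group) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Only the libraries of the contrast entered each fit, and all 14 entered the test of the difference between tissues. The SE of a log2 fold change was derived from this test, as its absolute value divided by the square root of F. The 95% limits of log2 fold changes were built from that SE. Gene lists were tested with camera of limma 3.58.1, 2-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists with 5 or more tested members. The 34 lists held 744 genes, of which 741 were found in the table. They covered 21 pathways and T cell states, markers of other cell types the sort could hold, sex-linked genes, and genes of RNA quality and cell handling. The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined. The list test of tumor against spleen was added after the data were seen, on the same lists. Single values in groups of 3 and 4 were compared with a 2-sided exact permutation test, whose smallest p is 0.029. CPM are counts scaled to the library's total after TMM adjustment. A gene at 0 in a group was given a fold against a floor of 3 counts over that group. With 1 to 3 counts, the ratio of the counts, each over its group's total counts, was given with an exact 95% interval. A floor of 3 counts in 1 library lay between 0.29 and 0.617 CPM of its unadjusted total.

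Named genes were, for each contrast within a tissue and for tumor against spleen, Il23r, Foxp3, Il2ra, Ctla4, Ikzf2, Il10, Ifng, Tbx21, Gzmb and Il17a, where counts allowed a test. Some genes that the rule names are not reported here. Up to 10 genes per direction with the largest changes were added among those that passed, whose groups did not overlap and whose average log2 CPM was 2 or more. Where fewer than 5 passed, the non-overlapping genes with the smallest p filled the number up to 5 and are said not to pass. Predicted genes and antigen receptor segments were counted and not named. In each list described, up to 6 passing members by p were named, or otherwise the 2 to 4 with the smallest p, and sex-linked and other-cell-type members wherever their list is described. The difference of contrasts names the 3 genes with the smallest p. Transcripts weighed in the closing tests outside these rules were chosen after their values were seen.

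Each gene test was tested on simulated data drawn from the real means and library sizes, with 200 genes changed, 50 at each of 2-fold, 4-fold, 8-fold and 16-fold. In the tumor simulation (10480 genes tested) 0% were recovered at each fold. In the spleen simulation (10739 genes) 0, 2, 12 and 40% were recovered, in that of the difference (11813 genes) 0, 0, 0 and 2%, and in that of tumor against spleen (10363 genes) 0, 0, 0 and 8%. False calls numbered 0, 1, 0 and 0. In a simulation of 30 lists of 30 genes in tumor, the 1 list shifted 4-fold was found and 0 others were called. Its genes were drawn independently of each other, so it did not test false calls of lists whose genes are correlated. With the spread between these libraries, a gene that did not pass can thus have changed many-fold. Libraries of a group were compared in pairs for duplicates, and none was found (chi-square per degree of freedom 92.1 to 391).

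Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE size factors, no filter, a filter of 5 CPM in at least 3 libraries, the replicate number as a block, all 14 libraries in 1 fit, an estimated inter-gene correlation, fry, and each library left out in turn. Because Xist and Y-linked reads occurred together in both WT replicate 2 libraries, fits without both were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the tests reported first.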

Results

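Regulatory T cells (Tregs), the CD4 T cells that express Foxp3 and restrain other lymphocytes, were sorted by a yellow fluorescent protein produced together with Foxp3. The mice carried flank tumors of MC38, a mouse colon carcinoma line, at the endpoint of tumor growth. Polyadenylated RNA of Tregs from spleen and from tumor was sequenced after ultra-low-input library preparation. In each tissue 4 libraries were labelled WT, with an intact Il23r gene, and 3 were labelled Flox, with Il23r alleles that a Foxp3-driven Cre recombinase is designed to delete in Tregs. Il23r encodes the specific subunit of the receptor for IL-23, a cytokine of inflamed tissue, and the series concerns what loss of this receptor does to Tregs inside tumors. The 14 libraries held between 4859099 and 10333892 counts. The Flox-labelled spleen libraries held 8942933, 7829623 and 10333892 counts, and the WT-labelled ones 8655980, 10208509, 8791465 and 4859099. In tumor the Flox-labelled libraries held 9756158, 8394109 and 10289905 counts, and the WT-labelled ones 6876211, 9829525, 7597383 and 10046884. Between 13657 and 15312 genes had at least 1 count in a library. The labels do not say that replicates were separate mice, so p-values measure only the spread between these samples.

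The deleted gene was read first. Il23r (NCBI Gene 209590, chromosome 6, 67422932 to 67491855 on GRCm38) was barely detected in any library, and in tumor its counts were higher in the libraries labelled Flox. In tumor, the 3 Flox-labelled libraries held 17 counts in total (0.641 ± 0.243 CPM, counts scaled to the TMM-adjusted library size, SD, n = 3) and the 4 WT-labelled libraries 2 counts (0.0539 ± 0.108 CPM, SD, n = 4). The ratio of counts over library totals was 10.3, with a 95% counting interval of 2.44 to 91.6. Each tumor Flox-labelled library lay above each WT-labelled one (two-sided exact permutation p = 0.0286, the smallest that 3 against 4 can give). In spleen the totals were 10 and 2 counts, a ratio of 6 with a counting interval of 1.28 to 56.3, at 0.299 ± 0.429 and 0.0511 ± 0.102 CPM (two-sided exact permutation p = 0.371). Of the 10 spleen counts 9 were in Flox replicate 3, and without that library the totals were 1 and 2 counts, too few for a ratio. These are counts over the whole gene, the deleted exons are not given in the sources used here, and the direction in tumor is opposite to what the labels imply. Libraries are therefore called Flox-labelled and WT-labelled throughout, and every direction drawn from them follows the labels. Intervals of such low counts, and floors set at 3 counts over a group, cover counting error only.

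Genes that tell male from female cells followed the genotype labels in both tissues. Xist, the noncoding RNA that silences 1 X chromosome in female cells, stood at 302 ± 245 CPM (SD, n = 4) in WT-labelled and 2.32 ± 0.852 CPM (n = 3) in Flox-labelled tumor libraries. In spleen it stood at 180 ± 165 and 0.752 ± 0.196 CPM. The Y-linked RNA helicase gene Ddx3y stood at 456 ± 151 CPM in Flox-labelled and 31.9 ± 63.3 CPM in WT-labelled tumor libraries, and at 319 ± 32.3 and 7.83 ± 14.8 CPM in spleen. The Y-linked genes Uty, Kdm5d and Eif2s3y were higher in each Flox-labelled than in each WT-labelled library of the same tissue, as Ddx3y was (two-sided exact permutation p = 0.0286 for each gene in each tissue), and Xist was lower in each (exact permutation p = 0.0857 in each tissue). In WT replicate 2 of the tumor Ddx3y reached 127 CPM, and in WT replicate 2 of the spleen it reached 30 CPM, beside at most 0.366 and 0.627 CPM in the other WT-labelled libraries of the tissue. Every Flox-labelled library had less Xist and more of these Y-linked reads than every WT-labelled one of its tissue, so no comparison of genotypes within 1 sex could be made. Reads of Xist and its antisense partner Tsix cannot be told apart, since the strand setting of the counting is not given in the sources used here.

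**Figure D1:**
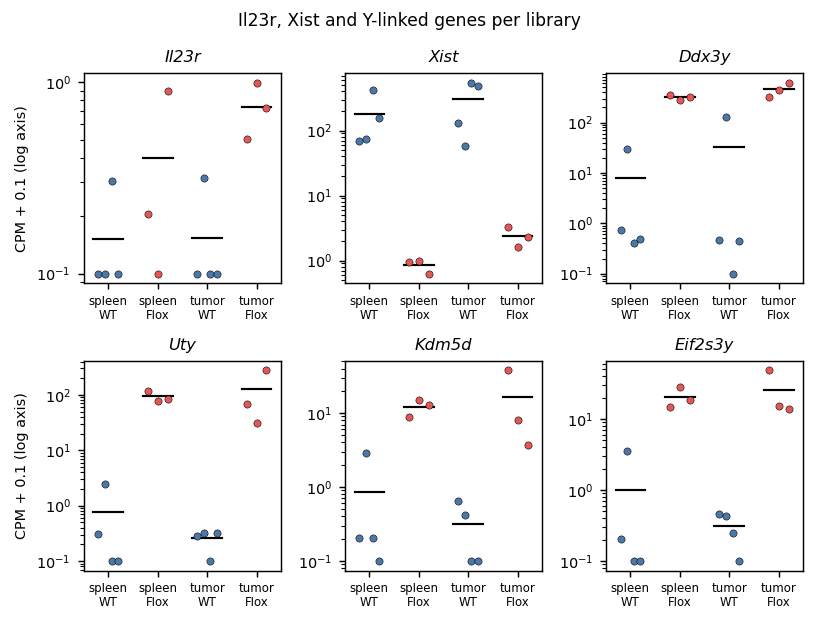
CPM of Il23r, Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y in each of the 14 libraries, with a small offset added and on a log axis. Each point is 1 library, black lines are group means, and blue and red mark WT-labelled and Flox-labelled libraries; Ddx3y is at 315 CPM or more in the Flox-labelled tumor libraries and at 127 CPM or less in the WT-labelled ones.

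The series' stated comparison is Flox against WT within a tissue. In tumor Tregs the genes that define the lineage and its effector functions differed by less than the test could call. Foxp3, the lineage transcription factor, stood at 128 ± 23.8 CPM (SD, n = 3) in Flox-labelled and 142 ± 61.9 CPM (n = 4) in WT-labelled libraries, a log2 fold change of -0.14 ± 0.54 (SE). Ikzf2, which encodes the Treg transcription factor Helios, had -0.29 ± 0.24. The high-affinity IL-2 receptor chain Il2ra had -0.59 ± 0.36 (1136 ± 367 against 1703 ± 491 CPM), and the inhibitory receptor Ctla4 had -0.86 ± 0.53 (688 ± 132 against 1246 ± 723 CPM). Among genes of effector function, the suppressive cytokine Il10 had 0.39 ± 0.75, the Th1 cytokine Ifng 0.50 ± 0.69, the Th1 transcription factor Tbx21 0.41 ± 1.31 and the cytotoxic protease Gzmb 0.35 ± 0.35. Tbx21 stood at 325 CPM in WT replicate 4, beside 11.2 to 20 CPM in the other WT-labelled and 60.9 to 170 CPM in the Flox-labelled libraries, and had a log2 fold change of 3.12 without WT replicate 4, which did not pass either. With 1 library left out, Foxp3 (0.18 without WT replicate 2), Il10 and Ifng (each -0.05 without Flox replicate 1) changed sign. Adjusted p for these 8 genes lay between 0.631 and 0.961 in edgeR's quasi-likelihood test. Il17a had 6 counts in WT-labelled and 1 in Flox-labelled libraries, a ratio of 4.97 with a counting interval of 0.603 to 229. These counts were too low to be tested.

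Of 10777 genes tested in tumor, edgeR passed 0 at an adjusted p under 0.05, with 871 genes at an unadjusted p under 0.05 (539 higher and 332 lower in Flox-labelled libraries). DESeq2 passed 193 (114 higher, 79 lower), among them 8 of the 18 genes that the naming rule gave here, and limma voom 1, Ankrd55. The smallest adjusted p in edgeR was 0.133, for Ankrd55, an ankyrin-repeat protein gene (NCBI Gene 77318, chromosome 13, 112288451 to 112384005), at 118 ± 53.3 CPM in Flox-labelled and 1.01 ± 0.189 CPM in WT-labelled libraries (log2 fold change 6.85 ± 0.68). Mpp2, a membrane-associated guanylate kinase gene (chromosome 11, 102057015 to 102088638), had 6.12 ± 0.82, and Btbd2 (chromosome 10, 80642623 to 80656494) had 4.52 ± 0.62. The Y-linked genes Uty (chromosome Y, 1085187 to 1245773) and Eif2s3y (chromosome Y, 1010562 to 1049134) had 9.51 ± 1.31 and 6.90 ± 0.98. These 4 genes had an adjusted p of 0.305. Lower in the Flox-labelled libraries at an adjusted p of 0.584 were Xist (-7.02 ± 1.17), the Rac exchange factor gene Dock5 (-7.54 ± 1.82), the methyltransferase gene Eef1akmt2 (-3.88 ± 0.95), the endocytosis gene Fcho2 (-2.26 ± 0.56) and Ddx5. Ddx5, an RNA helicase gene (chromosome 11, 106780355 to 106789185), stood at 1421 ± 259 against 3968 ± 1610 CPM, a log2 fold change of -1.49 ± 0.36. Dock5 stood at 452 CPM in WT replicate 4, beside 13.1 to 31.3 CPM in the other WT-labelled libraries, and had -4.93 without that library. In each of these 10 genes every Flox-labelled library lay beyond every WT-labelled one, as in 560 genes (5.2%) of those tested, where chance gives 5.7%. The biological coefficient of variation was 0.852, and the median SE of a log2 fold change was 0.743.

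Gene lists described the same libraries by pathway and cell type. Of 29 lists tested in tumor with camera, 2 passed, and 0 of the 21 lists of pathways and T cell states did. The sex-linked list was higher in Flox-labelled libraries (4 of 5 members, adjusted p = 3e-05), and 3 members higher and 1 lower passed when adjusted over the list alone. With an estimated correlation its adjusted p = 0.121. Markers of macrophages and monocytes were higher (14 of 20 members, median log2 fold change 0.51, adjusted p = 0.0155), and adjusted p = 0.533 with an estimated correlation. Their leading members were Cd68, a lysosomal glycoprotein gene of macrophages, at 20.6 ± 8.26 against 2.81 ± 1.35 CPM (log2 fold change 2.87 ± 0.54), the matrix gene Fn1 (1.64 ± 0.68) and the growth factor receptor Csf1r (2.68 ± 1.12). Only Cd68 passed when adjusted over the list alone, and 0 of the 20 passed over all genes. As in every genotype contrast here, the libraries compared also differed in Xist and Y-linked reads. The call was lost without Flox replicate 3 (adjusted p = 0.306), WT replicate 1 (adjusted p = 0.0571) or WT replicate 4 (adjusted p = 0.125), and its adjusted p over all alternatives ranged from 0.000862 to 0.533.

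The lists closest to the question of Treg stability did not pass in tumor, and 0 of their members passed over all genes or adjusted over the list alone. Treg identity and suppression had 11 of 27 members higher and 16 lower (adjusted p = 0.721), with Plagl1 at -1.84 ± 0.61, Socs2 at -1.89 ± 0.81 and Itgb8, which activates TGF-beta, at 1.58 ± 0.68. Th1 and cytotoxic effector genes had 22 of 27 members higher (adjusted p = 0.267), with the IL-12 receptor chain Il12rb2 at 2.49 ± 0.93 and the chemokine receptor Cx3cr1 at 3.66 ± 1.40. Il12rb2 stood at 86.1 CPM in Flox replicate 2, beside 5.6 and 12.7 CPM in the other Flox-labelled and 3.4 to 8.52 CPM in the WT-labelled libraries. The IL-23 and IL-12 receptor pathway had 3 of 11 higher (adjusted p = 0.571), with the receptor kinase Jak2 at -1.26 ± 0.41, at 300 ± 64.1 against 719 ± 201 CPM. Type I interferon response genes had 26 of 39 higher (adjusted p = 0.151), with Oasl1 at 3.21 ± 0.93 and Cmpk2 at 1.76 ± 0.74. Interferon-gamma response genes had 18 of 35 higher (adjusted p = 0.776), with Gbp4 at 2.09 ± 0.63 and Iigp1 at 1.76 ± 0.75. Cell cycle genes had 31 of 48 higher (adjusted p = 0.0841), with Cdk1 at 3.77 ± 0.91, Ccne1 at 3.20 ± 0.84 and Cdt1 at 3.08 ± 0.95. T cell receptor and NF-kB activation genes had 18 of 28 lower (adjusted p = 0.388), with Egr2 at -1.74 ± 0.47, Nfkb1 at -1.67 ± 0.62 and Nfkb2 at 1.61 ± 0.65. The list of immediate early and heat shock genes, which respond to cell handling, had 22 of 24 members lower in Flox-labelled libraries (adjusted p = 0.0543), with Hspa8 at -2.20 ± 0.86 and Egr1 at -1.76 ± 0.76.

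The remaining tumor lists did not pass either, and 0 of their members passed over all genes or adjusted over the list alone. Their adjusted p from camera follow. Follicular helper and regulatory genes (Tfh and Tfr) had 0.416. The mitochondrially encoded and IL-2 and STAT5 response lists had 0.631, and cytoplasmic ribosomal proteins 0.776. Chemokine receptors and homing, TGF-beta response, MC38 tumor cell markers, dendritic cell markers, cholesterol and lipid synthesis, nuclear oxidative phosphorylation and Th2 had 0.851. Th17 and the unfolded protein response had 0.859, and apoptosis and p53 had 0.882. Effector and tissue Treg genes and glycolysis and hypoxia had 0.904. Inhibitory receptors and resting or naive T cell genes had 0.929, and fibroblast and endothelial markers 0.945. Median or mean differed in sign from the test for 7 lists: effector Treg, resting, Th17, inhibitory receptors, dendritic cell and MC38 markers, and, for its mean, interferon-gamma response.

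**Figure D2:**
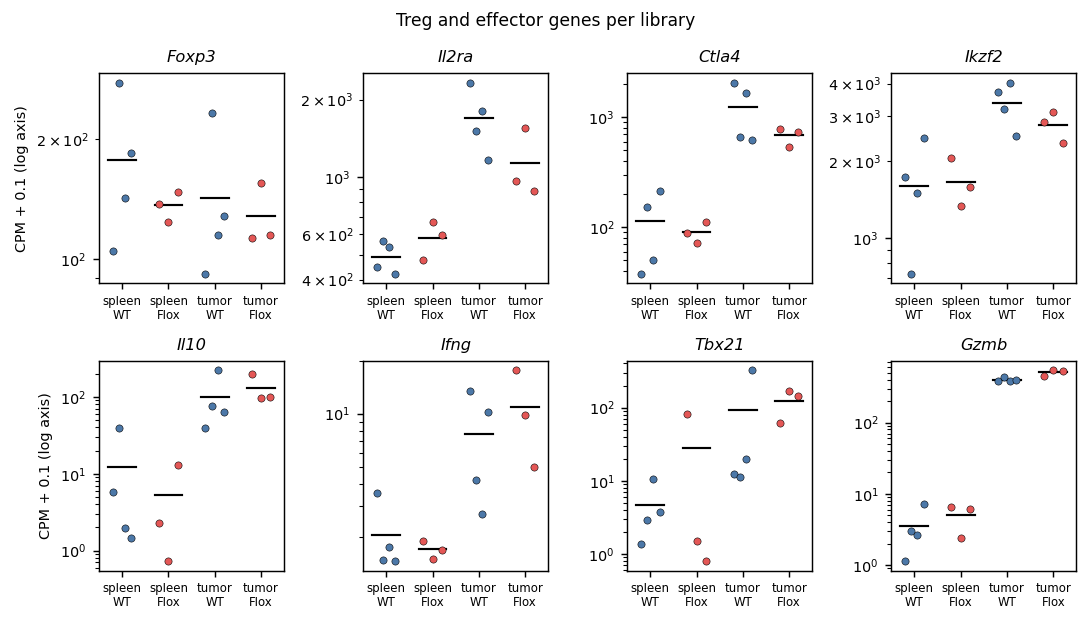
CPM of Foxp3, Il2ra, Ctla4, Ikzf2, Il10, Ifng, Tbx21 and Gzmb in each of the 14 libraries, with a small offset added and on a log axis. Each point is 1 library and black lines are group means; Foxp3 means lie at 142 and 128 CPM in WT-labelled and Flox-labelled tumor libraries, and Gzmb means in WT-labelled libraries lie at 3.41 CPM in spleen and 398 CPM in tumor.

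In spleen Tregs the same genes differed by less than the test could call. Foxp3, the lineage transcription factor, stood at 136 ± 11.6 CPM (SD, n = 3) in Flox-labelled and 177 ± 73.5 CPM (n = 4) in WT-labelled libraries (log2 fold change -0.39 ± 0.39, SE). Ikzf2 had 0.04 ± 0.37, Il2ra 0.23 ± 0.22 and Ctla4 -0.36 ± 0.65. Il10 had -1.23 ± 1.40, Ifng -0.31 ± 0.46, Gzmb 0.54 ± 0.68 and Tbx21 2.57 ± 1.51. Tbx21 stood at 80.6 CPM in Flox replicate 1, beside 0.703 and 1.39 CPM in the other Flox-labelled and 1.25 to 10.6 CPM in the WT-labelled libraries, and its log2 fold change became -2.14 without Flox replicate 1. Il10 stood at 39.6 CPM in WT replicate 2 and at most 5.64 CPM in the other WT-labelled libraries, and had 0.79 without WT replicate 2. Ifng (0.09 without WT replicate 1), Ctla4 (0.15 without WT replicate 4) and Ikzf2 (-0.14 without Flox replicate 1, -0.22 without WT replicate 2) also changed sign. Adjusted p for these 8 genes lay between 0.719 and 0.993 in edgeR, and Il17a had 0 counts in both groups.

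Of 10935 genes tested in spleen, edgeR passed 0, with 750 at an unadjusted p under 0.05 (465 higher and 285 lower in Flox-labelled libraries). DESeq2 passed 121 (78 higher, 43 lower), among them 10 of the 19 genes that the naming rule gave here, and limma voom 0. The smallest adjusted p was 0.114, for Wdr19, an intraflagellar transport gene (NCBI Gene 213081, chromosome 5, 65199696 to 65260415), at 9.30 ± 3.75 CPM in Flox-labelled and 0.306 ± 0.0732 CPM in WT-labelled libraries (log2 fold change 4.87 ± 0.49). Also higher without passing were the Deltex ubiquitin ligase gene Dtx4 (4.63 ± 0.59, adjusted p = 0.148), Phf11d (4.73 ± 0.68), the zinc finger gene Zfp747 (4.79 ± 0.78) and the thyroid hormone receptor gene Thrb (4.57 ± 0.78). Lower without passing were Xist (-7.90 ± 0.99), the inositol trisphosphate kinase gene Itpkc (-4.77 ± 0.78), the mitochondrial ribosome gene Dap3 (-2.29 ± 0.45), the bicarbonate transporter gene Slc4a10 (-5.96 ± 1.25) and Zfp113 (-4.79 ± 1.11). Adjusted p for the last 8 of these lay between 0.148 and 0.674. In each of the 10 genes every Flox-labelled library lay beyond every WT-labelled one, as in 653 genes (5.97%) of those tested, where chance gives 5.7%. Without WT replicate 2, which held Y-linked reads, edgeR passed 1 gene, the Y-linked Ddx3y.

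Of 30 lists tested in spleen, 3 passed with camera, among them 1 of the 21 lists of pathways and T cell states. Cell cycle genes were higher in Flox-labelled libraries (26 of 46 members, median log2 fold change 0.24, adjusted p = 0.00717, and adjusted p = 0.709 with an estimated correlation), with the replication factor gene Mcm10 at 4.07 ± 0.90, the spindle checkpoint kinase gene Bub1b at 4.44 ± 1.18 and Pbk at 2.86 ± 0.84. Markers of B cells and plasma cells were lower (14 of 17 members, median -1.29, adjusted p = 0.00629, and adjusted p = 0.709 with an estimated correlation), with the B cell inhibitory receptor Cd22 at -2.73 ± 0.79, the B cell transcription factor Ebf1 at -1.67 ± 0.52 and the antibody light chain gene Igkc at -1.29 ± 0.57. The sex-linked list was higher (4 of 5 members, adjusted p = 0.0035, and adjusted p = 0.709 with an estimated correlation), moving with the same labels. No member passed over all genes, and adjusted over the list alone 4 sex-linked genes passed as higher and 1 as lower, and 0 genes of the other 2 lists passed. The cell cycle call was lost without Flox replicate 1 (adjusted p = 0.135) or 3 (0.13), or WT replicate 2 (0.105) or 3 (0.0547), within a range of 3.28e-05 to 0.709 over all alternatives. The B cell call was lost without Flox replicate 3 (adjusted p = 0.0994) or WT replicate 2 (0.65), within a range of 6.26e-05 to 0.709. The number of lists moved to 1 without Flox replicate 3 or WT replicate 2, to 5 without Flox replicate 2 and to 8 without WT replicate 4.

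Other spleen lists did not pass. Cytoplasmic ribosomal proteins had 53 of 58 members lower (adjusted p = 0.0681), and apoptosis and p53 genes 17 of 22 lower (adjusted p = 0.0821), with the survival gene Bcl2l1 at 0.57 ± 0.16 and the death gene Bbc3 at -3.69 ± 1.61. The IL-23 and IL-12 receptor pathway had 7 of 11 higher (adjusted p = 0.112), with the receptor kinase Tyk2 at 1.02 ± 0.34 (397 ± 33.1 against 194 ± 66.7 CPM) and the shared receptor chain Il12rb1 at 1.21 ± 0.49. Macrophage and monocyte markers had 11 of 16 lower (adjusted p = 0.124), with the chemokine receptor Ccr2 at 2.74 ± 0.67, Adgre1 at -5.94 ± 2.25 and Cd68 at -3.41 ± 1.32. Ccr2 is on the effector and tissue Treg list as well. Adgre1 stood at 200 CPM in WT replicate 2 and at most 4.7 CPM in the other WT-labelled libraries, and Cd68 at 24.1 CPM in WT replicate 1 and at most 3.17 CPM in the others. Treg identity and suppression had 16 of 28 higher (adjusted p = 0.725), with the ectonucleotidase gene Nt5e at 0.99 ± 0.38 and the integrin gene Itgae at 1.38 ± 0.60. Type I interferon response genes had 28 of 39 lower (adjusted p = 0.36), with Isg15 at -1.20 ± 0.43 and Herc6 at 2.16 ± 0.79. Neutrophil markers had 5 of 5 lower (adjusted p = 0.282), and erythroid and platelet markers 4 of 6 lower (adjusted p = 0.819). Handling genes had 18 of 23 lower (adjusted p = 0.112). Adjusted p was 0.282 for Th1 and cytotoxic genes, 0.284 for chemokine receptors, 0.341 for dendritic cell markers and for effector Treg genes, and 0.384 for mitochondrially encoded genes. It was 0.725 for T cell receptor and NF-kB activation, glycolysis and TGF-beta response, and 0.819 for oxidative phosphorylation, Tfh and Tfr, Th17, inhibitory receptors and the unfolded protein response. It was 0.82 for IL-2 and STAT5 response, 0.836 for interferon-gamma response, 0.907 for Th2 and resting T cell genes and 0.934 for cholesterol synthesis. None of the lists in this group had a member that passed over all genes or adjusted over the list alone. Median, mean and test differed in sign for resting, Th17, Th2, inhibitory receptor, IL-2 and STAT5, glycolysis and erythroid genes.

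**Figure D3:**
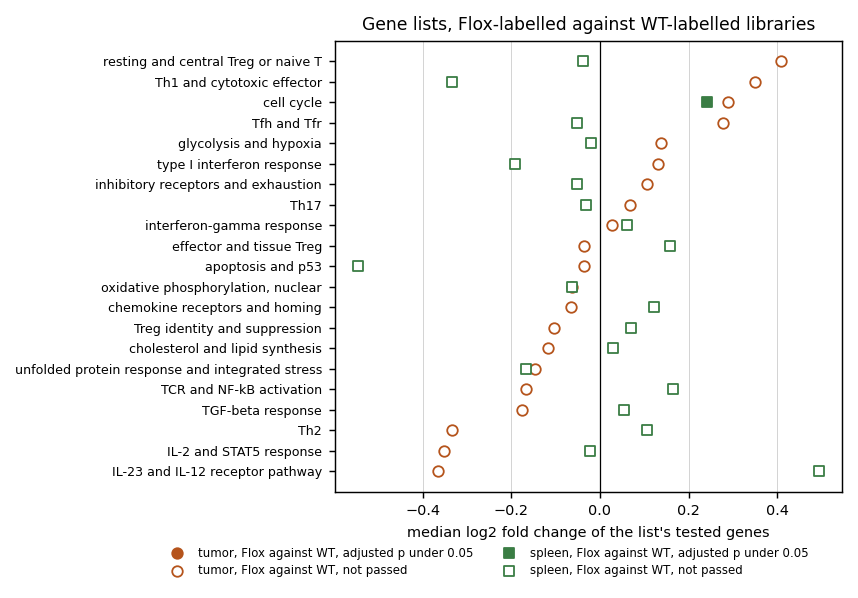
Median log2 fold change, Flox-labelled against WT-labelled libraries, of the genes of each pathway or T cell state list in tumor (circles) and spleen (squares). Filled symbols mark lists at an adjusted p under 0.05 in camera; the cell cycle list in spleen, with a median of 0.24, is the single filled one.

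Whether the genotype contrast itself differed between tumor and spleen was tested as a difference of the 2 contrasts. Ankrd55 stood at 118 CPM in Flox-labelled tumor libraries and between 1.01 and 6.24 CPM on average in the other groups, and Dtx4 at 75.7 CPM in Flox-labelled spleen libraries and between 1.2 and 3.02 CPM elsewhere. Of 12008 genes edgeR passed 0, with 1296 at an unadjusted p under 0.05 (625 higher and 671 lower in tumor), and DESeq2 passed 123 and limma voom 0. In edgeR the smallest p belonged to Dtx4 (difference -4.63 ± 0.77, SE), Ankrd55 (6.95 ± 1.21) and Itpkc (4.56 ± 0.87), with adjusted p between 0.395 and 0.425. These 3 passed with DESeq2. Of 33 lists, 1 passed: macrophage and monocyte markers, with 18 of 22 members higher in tumor relative to spleen (median 1.78, adjusted p = 0.00141), and adjusted p = 0.826 with an estimated correlation. Cd68 had a difference of 6.34 ± 1.48 and Ccr2 one of -3.12 ± 0.80, and these 2 genes, 1 in each direction, passed when adjusted over the list alone. Ccr2 is also on the effector and tissue Treg list, so its change cannot tell macrophages from Tregs. In spleen Cd68 stood at 24.1 CPM in WT replicate 1, beside 1.12 to 3.17 CPM in the other WT-labelled and 0.126 to 1.16 CPM in the Flox-labelled libraries. The call was lost without tumor Flox replicate 3 (adjusted p = 0.0886), within a range of 0.00013 to 0.826 over all alternatives, and the number of lists became 2 without spleen Flox replicate 2 or spleen WT replicate 4. The other 32 lists had adjusted p between 0.191 and 0.976, among them the IL-23 and IL-12 receptor pathway (4 of 11 higher, 0.197), type I interferon response (26 of 39 higher, 0.191), Treg identity (11 of 28 higher, 0.694), neutrophil markers (7 of 8 higher, 0.197) and natural killer cell markers (2 of 5 higher, 0.895). Adjusted over the list alone, 1 member passed in each of the neutrophil and natural killer lists as higher, and in each of the IL-23, effector Treg and chemokine receptor lists as lower. Median, mean and test differed in sign for inhibitory receptors, T cell receptor and NF-kB activation, glycolysis, oxidative phosphorylation, the unfolded protein response, handling and natural killer genes. The CD8 T cell list, with 2 members, was too short to test.

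Tumor Tregs were then compared with spleen Tregs in the WT-labelled libraries, as context for where the lists are expressed. The tumor libraries carried more transcript of effector and activation genes and less of resting T cell genes. Gzmb rose from 3.41 ± 2.62 CPM (SD, n = 4) in spleen to 398 ± 22.7 CPM (n = 4) in tumor (log2 fold change 6.95 ± 0.74, SE, adjusted p = 0.00399). Il2ra rose from 492 ± 68.4 to 1703 ± 491 CPM (1.88 ± 0.30, adjusted p = 0.011), and Ctla4 rose by 3.53 ± 0.73 on the log2 scale (adjusted p = 0.0249). Each of the 4 tumor libraries lay above each of the 4 spleen libraries for these 3 genes. Foxp3 had -0.25 ± 0.50, Ikzf2 1.15 ± 0.36, Ifng 2.04 ± 0.62, Tbx21 4.43 ± 1.40 and Il10 3.11 ± 1.19, and none of these passed (adjusted p between 0.0808 and 0.785). Without tumor WT replicate 4, at 325 CPM, Tbx21 had 1.74, and without spleen WT replicate 2 Foxp3 had 0.05 and Il10 passed at 5.16. Gzmb had 7.58 without spleen WT replicate 4. The Ctla4 call was lost without spleen WT replicate 1 or 3 or tumor WT replicate 3, at an adjusted p of up to 0.0665, within a range of 7.44e-05 to 0.121 over its alternatives. In edgeR 750 of 10560 genes passed, 412 higher and 338 lower in tumor. DESeq2 passed 2349 genes and limma voom 866. Groups did not overlap in 1914 genes (18.1%), where chance gives 2.9%. Leaving out 1 library gave 419 genes without spleen WT replicate 1, 373 without spleen WT replicate 3, 482 without tumor WT replicate 2 and 417 without tumor WT replicate 4.

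The genes with the largest changes included matrix, adhesion and B cell genes. Sox9, a transcription factor of epithelial progenitors (chromosome 11, 112782210 to 112787757), rose from 0.373 ± 0.378 to 172 ± 142 CPM (log2 fold change 8.98 ± 1.38, adjusted p = 0.00911). The adhesion gene Ncam1 rose by 8.70 ± 1.31, the receptor kinase gene Kit by 8.55 ± 1.61, the adaptor gene Bcar1 by 9.51 ± 1.99 and the endoplasmic reticulum receptor gene Kdelr3 by 8.13 ± 2.04, on the log2 scale. The matrix genes Dcn (decorin), Col6a3 and Col6a2 and the chemokine Ccl2 had 1 or 2 counts in spleen, and their tumor to spleen ratios, with counting intervals, were 644 (115 to 25500), 431 (76.9 to 17000), 240 (66.2 to 1990) and 359 (99.1 to 2970). Ccdc184 had a ratio of 674 (121 to 26700). Of the genes lower in tumor, Ms4a1, which encodes the B cell antigen CD20, fell by 9.03 ± 1.60 on the log2 scale, the B cell kinase gene Btk fell by 8.33 ± 1.60 and Aff3 fell by 8.41 ± 1.25. The complement receptor gene Cr2, the IgM receptor gene Fcmr and the B cell adaptor gene Bank1 had 0 counts in tumor and were at least 437-fold, 131-fold and 122-fold lower. Hcn3, Sarm1, Pheta2 and Degs2 had 1 to 3 counts in tumor, and spleen to tumor ratios of 1080 (193 to 42700), 775 (265 to 3760), 637 (218 to 3090) and 507 (140 to 4190). These 20 genes had adjusted p between 0.00399 and 0.0465, and each was higher, or lower, in every tumor than in every spleen library. With 1 library left out the call was lost for 9 of the 20, at adjusted p of 0.0506 to 0.112, within a range of 5.19e-11 to 0.131 over their alternatives. This held for Bcar1 without any 1 spleen library, Kdelr3 without any 1 spleen library or tumor replicate 1 or 3, Kit without spleen replicate 1, 3 or 4, Cr2 without spleen replicate 1 or 3, Fcmr and Bank1 without these or tumor replicate 2, 3 or 4, Sarm1 without spleen replicate 3 or tumor replicate 2, 3 or 4, Dcn without spleen replicate 3 and Hcn3 without tumor replicate 2. Without tumor replicate 4 Bcar1 had 8.15, Kit 7.08, Ncam1 7.94, Ms4a1 -10.21 and Btk -9.51, and without tumor replicate 1 Kdelr3 had 6.26 and Sox9 8.24. Without spleen replicate 1 Bcar1 had 10.73 and Kdelr3 8.78, without spleen replicate 2 Kit had 9.15, Ms4a1 -7.98 and Btk -6.72, and without spleen replicate 4 Aff3 had -7.45. In tumor replicates 1 to 4 Kdelr3 stood at 247, 1.4, 66.5 and 1.36 CPM and Bcar1 at 3.84, 95, 2.6 and 233 CPM.

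Among the fixed lists, 25 of 30 passed with camera in this contrast, 19 higher and 6 lower in tumor, and 14 held with an estimated correlation, whose adjusted p is given beside each. Effector and tissue Treg genes rose (11 of 24 members passed over all genes and 18 adjusted over the list alone, none lower, adjusted p = 5.45e-16, and adjusted p = 0.00645 with an estimated correlation). Their leading members were the transcription factor genes Id2 (2.96 ± 0.25) and Maf (2.76 ± 0.28), Gzmb, the chemokine receptor Ccr2 (6.51 ± 0.75), and the repair factor Areg (6.08 ± 0.75). Resting and naive T cell genes fell (9 of 21 members, 11 adjusted over the list alone, adjusted p = 9.11e-09, and adjusted p = 0.014 with an estimated correlation). Tcf7, the transcription factor TCF-1, fell from 1082 ± 105 to 7.35 ± 5.23 CPM (-7.11 ± 0.62), and Bach2 (-6.54 ± 0.66), Foxp1 (-3.05 ± 0.36), Nsg2 (-4.64 ± 0.88), Bcl2 (-4.53 ± 0.86) and Id3 (-2.33 ± 0.48) fell too. Treg identity and suppression rose (8 members up and 1 down of 28, 15 and 3 adjusted over the list alone, adjusted p = 1.98e-06, and adjusted p = 0.00983 with an estimated correlation). Icos, a costimulatory receptor, rose by 3.87 ± 0.43, Fgl2 by 4.10 ± 0.57, Tnfrsf4 by 2.57 ± 0.44 and Tnfrsf9 by 2.28 ± 0.42, and the receptor gene Gpr83 fell by 6.59 ± 0.86. Th1 and cytotoxic effector genes rose (9 up and 1 down of 24, 17 and 1 adjusted over the list alone, adjusted p = 1.12e-10, and adjusted p = 0.00983 with an estimated correlation), with the chemokines Ccl3 (5.97 ± 0.56), Ccl4 (6.20 ± 0.72) and Ccl5 (2.59 ± 0.54), Nkg7 (4.07 ± 0.57) and Gzmc (1.99 ± 0.41). Each of these 4 lists passed with any of the 8 libraries left out, and each gene named from them passed over all genes with every tumor library beyond every spleen library.

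Glycolysis and hypoxia genes were higher in the tumor libraries too (19 of 31 members, 23 adjusted over the list alone, none lower, adjusted p = 3.24e-17, and adjusted p = 0.00645 with an estimated correlation). The mitophagy gene Bnip3 rose from 1.81 ± 0.998 to 46.5 ± 5.06 CPM (4.76 ± 0.60), the glycolytic enzyme genes Tpi1, Pgam1 and Aldoc by 4.19 ± 0.63, 2.95 ± 0.43 and 2.76 ± 0.42, and Ndrg1 and Ero1a by 4.55 ± 0.69 and 5.58 ± 0.89. Type I interferon response genes rose (12 of 39, 22 adjusted over the list alone, adjusted p = 6.29e-12, and adjusted p = 0.00983 with an estimated correlation), with Ifi27l2a at 2.99 ± 0.42, Ifit3 at 2.85 ± 0.45, Isg20 at 2.79 ± 0.49, Isg15 at 2.64 ± 0.46, Irf7 at 2.60 ± 0.47 and Bst2 at 2.44 ± 0.43. Also passing with both correlations were T cell receptor and NF-kB activation (adjusted p = 1.79e-06, estimated-correlation adjusted p = 0.0191), interferon-gamma response (6.61e-06 and 0.0151), cell cycle (4.35e-05 and 0.0367) and Th17 genes (0.000614 and 0.0252), all higher, and Tfh and Tfr genes, lower (0.00016 and 0.0191). Of their members 10 up and 1 down, 6 up, 3 up, 4 up, and 1 up and 3 down passed over all genes, and 11 and 2, 9 and 0, 7 and 0, 4 and 1, and 1 and 7 adjusted over the list alone. Only 8 of the 20 Th17 genes had counts enough to be tested here, 6 higher and 2 lower, and Il17a could not be tested. The IL-23 and IL-12 receptor pathway was higher (2 of 11 members over all genes, 5 up and 1 down adjusted over the list alone, adjusted p = 0.035), and adjusted p = 0.212 with an estimated correlation. Jak2 rose from 92 ± 41.2 to 719 ± 201 CPM (3.04 ± 0.47) and Stat3, which relays IL-23 signals, from 258 ± 89.8 to 837 ± 241 CPM (1.78 ± 0.41). That call was lost without spleen WT replicate 2, tumor WT replicate 2 or tumor WT replicate 3, up to an adjusted p of 0.103.

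Markers of other cell types moved with the same contrast. How much of the changes given above came from Tregs and how much from such cells was not tested. B cell and plasma cell markers fell in tumor (9 of 13 members, 11 adjusted over the list alone, adjusted p = 6.82e-12, and adjusted p = 0.0319 with an estimated correlation), with Igkc at -3.97 ± 0.63 and Cd79a at -5.13 ± 1.01, and with a spleen to tumor ratio of 202 (68.7 to 981) for Jchain. Their median log2 fold change was -6.74, also with the 2 members at 0 counts in tumor set to their bound. Fibroblast and endothelial markers rose (4 of 6 over all genes and 4 adjusted over the list alone, adjusted p = 4.29e-05, and adjusted p = 0.02 with an estimated correlation), with Sparc at 4.28 ± 0.52, Col6a1 at 6.45 ± 1.06, Col3a1 at 7.90 ± 1.40, and Dcn. MC38 tumor cell markers rose (3 of 6 over all genes and 3 adjusted over the list alone, adjusted p = 0.00127, and adjusted p = 0.0347 with an estimated correlation), with Areg, Sox9 and Tm4sf1, which was at least 16.7-fold higher, and their median of 3.21 became 2.2 with Tm4sf1 at its bound. Areg is also on the effector and tissue Treg list, so its rise cannot tell tumor cells from Tregs. Erythroid and platelet markers were lower (0 of 5 over all genes and 4 adjusted over the list alone, adjusted p = 0.000937, and adjusted p = 0.206 with an estimated correlation), and macrophage and monocyte markers higher (0.0325 and 0.212). The lists of handling genes (0.00145 and 0.212) and of the unfolded protein response (0.00294 and 0.0966) were higher, and those of ribosomal proteins (0.00298 and 0.53) and mitochondrially encoded genes (0.0321 and 0.423) lower. Cholesterol synthesis (0.0342 and 0.212), chemokine receptors (0.047 and 0.206), IL-2 and STAT5 response and apoptosis and p53 (each 0.047 and 0.119) were higher. Of these, 7 calls were lost with a library left out. The ribosomal list was lost without spleen WT replicate 2 (adjusted p = 0.0624) and the mitochondrial one without spleen or tumor WT replicate 2 (up to 0.159). Apoptosis was lost without spleen WT replicate 4 or tumor WT replicate 2 (up to 0.0668), macrophage markers without either of these or tumor WT replicate 3 (up to 0.101), and cholesterol synthesis without either of these or spleen WT replicate 1 (up to 0.0768). Chemokine receptors were lost without spleen WT replicate 1, 3 or 4 or tumor WT replicate 2 or 4 (up to 0.115), and IL-2 and STAT5 response without any spleen library or tumor WT replicate 2 or 3 (up to 0.111). Inhibitory receptors (adjusted p = 0.054), Th2 (0.0651), oxidative phosphorylation (0.0758), dendritic cell markers (0.106) and TGF-beta response (0.121) did not pass.

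**Figure D4:**
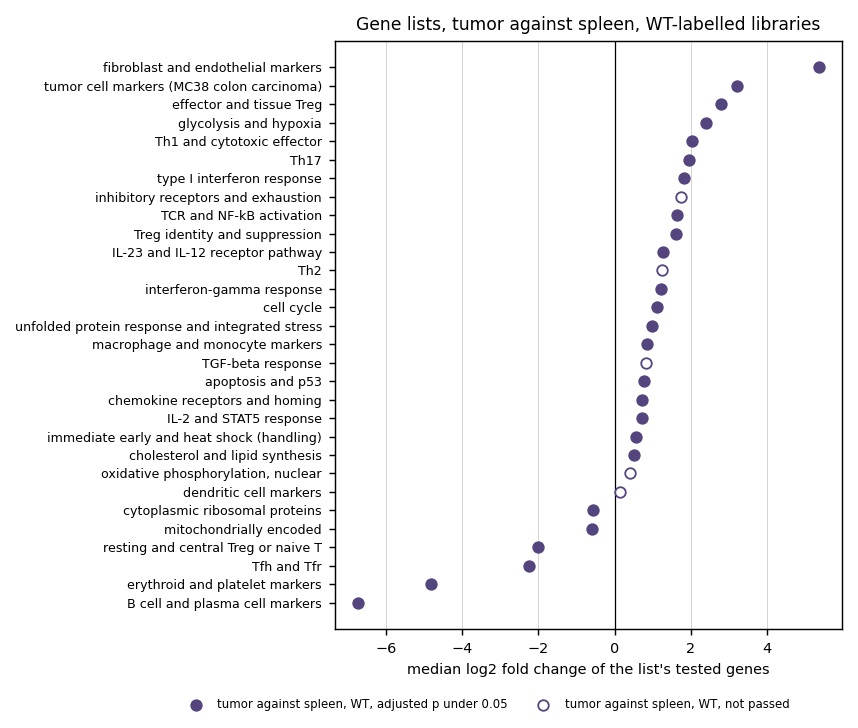
Median log2 fold change, tumor against spleen in WT-labelled libraries, of the genes of each list. Filled circles mark lists at an adjusted p under 0.05 in camera and open circles the others; medians run from -6.74 for B cell and plasma cell markers to 5.37 for fibroblast and endothelial markers.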

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

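The tests of swapped and exchanged labels, of Y-linked reads in the WT replicate 2 libraries, of macrophage transcripts and of counting error were chosen only after the result was seen.

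Xist and Y-linked genes followed the genotype labels in both tissues and Il23r counts in tumor, where they were higher in the libraries labelled Flox. For Xist, or for 3 or more of the 4 Y-linked genes, 0 of 14 libraries lay within the other label's range. This restates the separation by label. It argues against single libraries swapped between the labels only if sex marks genotype, which is not given in the sources used here. Genotype labels exchanged between the whole groups stay open, because each Flox-labelled library lay above every WT-labelled one for Il23r in 1 of the 2 tissues, on few counts over a gene whose deleted exons are not given. Xist and the Y-linked genes are themselves what animals of different sex in the genotype groups would give, with the labels right or exchanged. X-linked genes expressed from both X chromosomes (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) could neither add to this nor argue against it. Of these, 4 of 8 values were lower in Flox-labelled libraries, which met the bound set against different sexes. With standard errors of 0.401 to 0.913 none of the 8 lay more than 2 standard errors from no change. Kdm5c lay farthest on that scale, at -1.5 ± 0.913 in tumor and -0.839 ± 0.513 in spleen (log2 fold change, SE). A requirement on the intervals was added after the 4 of 8 was seen. Male cells or RNA mixed into that library is a candidate explanation for spleen WT replicate 2, where 4 of 4 Y-linked genes exceeded 3 times the highest other WT library, at 2.57 to 23.2% of the Flox-labelled mean. In tumor WT replicate 2 only 1 of 4 did (Ddx3y, at 27.8%, beside 0.171 to 1.96% for the others), which met the bound set against it. There the explanation stays open, since the test takes the 4 genes to scale alike. Among the Flox-labelled tumor libraries Uty ran from 30.4 to 281 CPM and Kdm5d from 3.59 to 38 CPM.

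Although the sort selected FoxP3-YFP-positive cells, a list of another cell type passed with the preset correlation in each tissue, B cells in spleen and macrophages in tumor, and neither held with an estimated correlation (adjusted p = 0.709 and adjusted p = 0.533). For the lower B cell list of the Flox-labelled spleen libraries, B cells or their RNA in WT replicate 2 alone is a candidate explanation for the call but not for each member, since the adjusted p became 0.65 and the median -0.23 without that library, within a range of 6.26e-05 to 0.709 over the alternatives; the call was also lost without Flox replicate 3 (adjusted p = 0.0994). Other libraries contribute too, since Ebf1 stood at 582, 946, 485 and 167 CPM, Igkc at 38.9, 109, 51.5 and 31.1 CPM and Cd22 at 9.41, 24.9, 31.2 and 75.7 CPM in WT replicates 1 to 4, beside 160 to 181, 18.2 to 30.8 and 3.69 to 6.95 CPM in the Flox-labelled libraries; 17 of the list's 20 genes were tested in spleen and 4 in tumor. The macrophage call in tumor was also lost without Flox replicate 3 (adjusted p = 0.306), WT replicate 1 (0.0571) or WT replicate 4 (0.125), within a range of 0.000862 to 0.533 over its alternatives; more macrophages or their RNA in the Flox-labelled sorts would raise abundant macrophage transcripts about as much as Cd68 (2.87), and 8 of 8 had a log2 fold change under its lower limit of 1.62 (Ctsb 86.8 and 97.5 CPM, Apoe 23.1 and 64.5 CPM in WT-labelled and Flox-labelled libraries). For 7 of the 8 the upper limit also lay under 2.87. This cannot decide whether macrophages were the source of the whole Cd68 change. Cd68 was the list's leading member, and its own interval was 1.62 to 4.13. The 8 were chosen after their values were seen and left out Csf1r of the list. Of the 8, C1qa, C1qb and Tyrobp stood at only 2.74, 1.86 and 1.88 CPM in WT-labelled libraries. A smaller share behind the list's median of 0.51 stays open too, since the median of the 8 was 0.34 and the interval of Apoe reaches 3.49. No biological explanation by Il23r can be separated from sex.

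Libraries of 1 group differed widely in both tissues. Counting error at this depth is argued against as the whole cause. Genes with 500 or more mean counts had a median biological coefficient of variation, the spread left after counting error, of 0.519 in spleen and 0.848 in tumor. Counts drawn with counting error alone gave the same 0.00988 in both tissues. That lies at the lower edge of the values the estimate could take, so it is a floor and not a measured spread. Few captured molecules, with longer transcripts sampled less completely, stay open: the mean rank correlation of dispersion across genes was 0.127 or more with exonic length and 0.15 or more with genomic span, between the bounds set for and against it, and genes are not independent replicates. Differences between mice were not tested and may contribute as well.

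Other splits of the libraries showed whether chance can be excluded. For tumor genes at an unadjusted p under 0.05, 35 of 35 splits gave as many as the real 871 (highest other 1321), and for spleen genes 28 of 35 gave 750 or more (highest other 993), so chance was not excluded. It was not excluded for lists in tumor (4 of 35 splits, real 2, highest other 2) or spleen (9 of 35, real 3, highest other 8), nor for the difference between tissues (64 of 100 splits for genes, real 1296, highest other 1664; 59 of 100 for lists, real 1, highest other 6). With DESeq2, on genes kept by edgeR's filter, 24 of 24 splits gave as many as the real 266 in tumor (highest other 611) and 22 of 24 as many as the real 125 in spleen (highest other 222). For tumor against spleen chance was excluded, with 1 of 35 splits, the real one, giving as many genes (real 750, highest other 2) and lists (real 25, highest other 19).

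The gap of a single library to the nearest of the other 3 was divided by the range of the group. In 29 of 199 values it was above Dixon's limit for 4 samples. About 1 in 20 (9.9) would be for independent, normally distributed values. CPM of genes in the same libraries need not be so, and 29 is therefore no measure of an excess over chance. Of the 29, 12 were in spleen WT replicate 2. In that library Il10 stood at 39.6, Uty at 2.41, Ddx3y at 30, Kdm5d at 2.81, Eif2s3y at 3.45, Mcm10 at 10.8, Adgre1 at 200, Bbc3 at 127, Fcmr at 23.7, Bank1 at 21.2 and Col6a1 at 0.321 CPM, and mitochondrially encoded genes took 1.13% of counts. In spleen WT replicate 1 Ifng stood at 3.45, Bub1b at 9.72 and Cd68 at 24.1 CPM, in replicate 3 Herc6 at 63.5 CPM and in replicate 4 Ero1a at 28.2 CPM. In tumor WT replicate 4 Tbx21 stood at 325, Dock5 at 452 and Ccr2 at 5530 CPM, and in replicate 3 Iigp1 at 151 CPM. In tumor WT replicate 2 Ddx3y stood at 127, Gbp4 at 82, Ccdc184 at 52.3, Pgam1 at 36.7 and Tpi1 at 211 CPM, and in replicate 1 Socs2 at 604, Ccl2 at 6.77 and Tcf7 at 15.2 CPM. Such a value can lie close to the others where these lie closer still, as Pgam1 did beside 38.6 CPM in the nearest library. Adgre1, a member of the macrophage list, was not among the values tested in tumor. It stood at 143.5 CPM in tumor WT replicate 2, beside at most 1.15 CPM in the other WT-labelled and 3.82 CPM in the Flox-labelled tumor libraries. The contrast of Flox-labelled with WT-labelled libraries differed between tissues for the macrophage list, by a camera test of the difference itself (adjusted p = 0.00141). For 18 of 22 members that contrast was higher in tumor than in spleen. With an estimated correlation the adjusted p = 0.826.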

How the results depend on the processing

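The fits without both WT replicate 2 libraries, and the list tests of tumor against spleen, were chosen only after the data were seen. DESeq2 passed 193 genes in tumor, 121 in spleen, 123 for the difference and 2349 for tumor against spleen, where edgeR passed 0, 0, 0 and 750. Limma voom passed 1 gene in tumor, the stricter filter 1 gene in spleen (Wdr19), and the fit of all 14 libraries 4 genes in spleen (Dtx4, Itpkc, Wdr19 and Xist) and 1514 for tumor against spleen. The cause was not tested. With an estimated correlation 0 lists passed in tumor, 0 in spleen, 0 for the difference and 14 for tumor against spleen, and with fry 1, 0, 0 and 27. Without both WT replicate 2 libraries, tumor against spleen passed 329 genes, with fewer samples, and the difference 2 lists. Leaving out each library in turn gave 0 genes in tumor each time, 0 to 1 in spleen, 0 to 1 for the difference and 373 to 658 for tumor against spleen, and 1 to 3, 1 to 8, 0 to 2 and 18 to 26 lists. Whether the replicate numbers pair the samples stays open. Over 13 same-numbered pairs the correlation of deviations was -0.0369 to 0.0447, and 4 of 13 correlated best with their own number. Only pairs of spleen with tumor under the same label could come from 1 mouse. Among these, 2 of 4 WT-labelled pairs (-0.0176 to 0.0447) and 0 of 3 Flox-labelled pairs (-0.0369 to -0.00518) correlated best with their own number. With the spread between these libraries, such values cannot exclude shared mice. With the replicate block, 1 list passed in tumor, 6 in spleen and 173 genes for tumor against spleen.

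RLE size factors and no filter left 0 genes in tumor, spleen and the difference, and gave 751 and 513 for tumor against spleen. Of the named genes' values under alternatives, 3 of 198 changed sign in tumor, 8 of 209 in spleen, 0 of 54 for the difference and 1 of 363 for tumor against spleen. A call was gained by 8 values in tumor, 14 in spleen and 3 for the difference, of which 8, 10 and 3 were with DESeq2. The other 4 in spleen were with all 14 libraries in the fit. For tumor against spleen 53 lost and 5 gained their call, and no called value changed sign. Depth limits genes of a few counts such as Il23r and Il17a, for which only large ratios were detectable.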

Other observations

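The contrast of tumor with spleen in the Flox-labelled libraries, and the comparison of its genes with those of the WT-labelled libraries, were tests chosen only after the data were seen. No gene list was tested in the Flox-labelled contrast. Gzmb rose in these libraries, from 4.96 ± 2.34 CPM (SD, n = 3) in spleen to 507 ± 47.3 CPM (n = 3) in tumor (log2 fold change 6.79 ± 0.60, SE, adjusted p = 0.0145 in edgeR). Ctla4 rose by 3.05 ± 0.35 (adjusted p = 0.0164), Icos by 3.58 ± 0.37, Id2 by 3.02 ± 0.34, Maf by 2.89 ± 0.30, Ccr2 by 3.41 ± 0.33 and the hypoxia gene Bnip3 by 5.11 ± 0.51. Ifng, which did not pass in WT-labelled libraries, rose by 2.86 ± 0.58, and the test of the difference between the 2 contrasts passed 0 genes in edgeR (1296 at an unadjusted p under 0.05, and 123 with DESeq2). Tcf7 fell by 6.96 ± 1.10, Bach2 fell by 5.66 ± 0.81 and Foxp1 fell by 1.96 ± 0.37. Adjusted p for these 11 genes lay between 0.0145 and 0.0355, and each tumor library lay beyond each spleen library. Foxp3 had 0.03 ± 0.40, Il2ra 1.08 ± 0.30 (adjusted p = 0.0771), Jak2 0.68 ± 0.49 (adjusted p = 0.418) and Stat3 1.36 ± 0.35 (adjusted p = 0.064), and none of these 4 passed. Each of the changes named as rising or falling here had the same sign in WT-labelled libraries.

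In the Flox-labelled contrast 847 of 10760 genes passed in edgeR, 447 higher and 400 lower in tumor. Of the 719 genes that passed in WT-labelled libraries and were tested here, 668 (92.9%) had the same direction. In both contrasts 225 genes passed as higher, where independent lists would share 15.1, and 94 as lower, where they would share 11.4, and 0 passed in opposite directions. The contrasts shared no libraries, and log2 fold changes had r = 0.525 across 10263 genes, which are not independent replicates.

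The genotype contrasts of tumor and spleen, which shared no libraries either, had r = 0.0112 across 9882 genes. At an unadjusted p under 0.05 in both, 22 genes were higher in both tissues, where independent lists would share 20.3, and 14 were lower, where they would share 7.04. A chromosome 6 segment carried along with the floxed allele was a hypothesis tested within 10 Mb of Il23r. There 0 of 47 genes, against 36 of 9835 elsewhere, had an unadjusted p under 0.05 with the same direction in both tissues (two-sided Fisher's exact p = 1), and with an upper limit of the odds ratio at 23.3 such a segment stays open.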
